A study of Mus musculus with 6 samples.

How the data were processed

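Messenger RNA was profiled in T lymphocytes taken from mouse spleen with CD90 magnetic beads, after red blood cell lysis, and cultured in RPMI medium with fetal bovine serum, per the labels' protocols. RNA was extracted with Trizol and libraries were made with an Ion Proton RNA-Seq kit. There were 3 libraries at 0 h of LZ-8 and 3 at 5 h. The deposited table holds whole-number read counts per gene symbol, not normalized, as its values show. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program, the annotation and the strand setting are not given in the sources used here. Without the strand setting, reads of overlapping or antisense genes cannot be told apart, and reads that match a gene and its copies may have been divided, doubly counted or dropped. Rows annotated as pseudogenes were 5 of the 30 most abundant rows, and Gapdh, which has many processed copies, had a mean of only 252.3 counts per library. Ion Proton reads carry no molecular identifiers here, so intervals and floors cover counting error only. The floors cover it for the 0 h group alone.

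Columns were matched to samples by their titles, and 0 columns were left unmatched. Of 44788 rows, 26310 had at least 1 count. Symbols were matched to GENCODE M21, on the mm10 assembly, for coordinates, biotype, transcript length and GC content (32213 rows matched), and 8156 rows were annotated as pseudogenes. Coordinates are those of the gene, 1-based. Mitochondrial genes are named as in the table, without coordinates. Total counts were 10779921, 12603650 and 14257045 at 0 h and 15419777, 16957163 and 17883187 at 5 h, with 21353 ± 345 and 21040 ± 121 rows detected (mean ± SD, n = 3 each). Fold changes of genes with few counts are the least precise: a count of 0 over the 0 h group allows up to 3 counts, or 0.0797 CPM (counts-per-million).

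Replicates were compared before use. The correlation of log2 CPM across genes, which are not independent replicates, was 0.986 to 0.993 within groups and 0.875 to 0.883 between them. The index of dispersion of paired counts, which is 1 for counting noise alone and otherwise grows with depth, was 3.11 to 5.6 between 0 h libraries, 7.77 to 27.1 between 5 h libraries and 243.1 to 307.5 between groups, so no pair agreed within counting noise and each library was counted as 1 sample. The first principal component held 90.3% of the variance and separated the times; the second, with 4.05%, separated 5 h replicate 1 from 5 h replicate 3.

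The test was edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F test with TMM scaling, the filterByExpr filter (minimum count 10) and group as the only term, with Benjamini-Hochberg adjustment at 0.05. The filter left 14930 genes. Log2 fold changes are 5 h over 0 h; standard errors are the fold change divided by the square root of F. The biological coefficient of variation was 10.1%, with 4 residual degrees of freedom per gene. CPM values are TMM-scaled. The floor, the count ratio of Slc7a11 and folds against the floor use total counts instead, without TMM scaling. Changes are relative to the scaling: the median of all genes moved by -0.0138 with size factors as in DESeq2, by -0.127 with upper-quartile scaling and by 0.150 with total counts only (log2), and 50.7%, 50.1%, 44.8% and 57.7% of called genes were higher with TMM and with these in turn.

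The question, test, gene lists, named genes and alternatives were fixed before the data were examined, except where stated. There were 26 lists with 593 symbols, of which 589 were found, 22 under another symbol. The 25 with at least 3 tested members were tested with camera (limma 3.58.1, two-sided, on log2 CPM with a prior count of 2) with a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, each adjusted over the lists. Camera asks whether a list ranks apart from all other genes, and fry whether its genes move one way on balance. With an estimated correlation, camera's test has only the 4 residual degrees of freedom, far fewer than with the preset value. The genes named are the 10 with the largest rise and the 10 with the largest fall among genes past the threshold whose groups did not overlap and whose mean count was at least 50, without predicted or clone-named models, histone genes and ribosomal-protein-like copies. Added to these are up to 4 members per list with the lowest adjusted p, and Isg15, Ifit1, Rsad2, Irf7, Ifnb1, Ifng, Il2, Il2ra, Cd69, Ddx58 and Thy1 whatever their values. A few genes that the rule or a count would name are not reported here. The closing section also uses 8 lists that were chosen after the values were seen.

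The fit was tested on simulated counts for this comparison, with 200 of 14640 genes changed. Of 50 genes each, it recovered 56% at 1.5-fold, 88% at 2-fold, 98% at 4-fold and 100% at 8-fold, and 11 of its calls (6.04%) were unchanged genes. Of 20 unchanged simulated lists, 0 were called by camera or fry. Simulated genes were drawn independently of each other and few were changed, unlike in these data. These shares therefore do not measure error rates where genes are correlated and most change. Alternatives were other scalings, DESeq2 1.42.0, limma-voom, no filter and a filter at 10 CPM in 3 or more libraries, a replicate block, each library left out, and a test against a 1.5-fold change. Chosen after seeing the data were thinning to the smallest library total, leaving out pseudogene rows, and scaling without heat shock, ribosomal RNA-like and mitochondrial rows. Bootstrap intervals are 95%, from 2000 draws of list members. They treat members as independent and hold no spread between libraries, so they can be too narrow. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.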

Results

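RNA sequencing measured gene expression in T lymphocytes from the spleens of female BALB/c mice. The cells were isolated with magnetic beads against CD90, a surface protein of T cells, and treated with LZ-8 for 0 h or 5 h. LZ-8 (Ling Zhi-8) is an immunomodulatory protein of the medicinal fungus Ganoderma lucidum. Each time had 3 libraries. Total counts were 10779921 to 14257045 in the 0 h libraries and 15419777 to 17883187 in the 5 h libraries, so each 5 h library was deeper than each 0 h library. Of 44788 gene rows, 26310 had at least 1 count and 14930 were tested. The comparison of 5 h with 0 h asks which genes respond to LZ-8, and the series title names antiviral innate immunity as its subject. No library of untreated cells kept for 5 h is among the samples, so LZ-8 treatment and 5 h of culture after isolation changed together.

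The profile of the cells differed widely between the times. Genes that import or make amino acids, the T cell growth factor gene Il2 and its receptor gene Il2ra were among those that rose, and heat shock genes and genes of resting T cells were among those that fell. At an adjusted p under 0.05, edgeR's quasi-likelihood test called 11005 genes (73.7% of those tested), 5584 higher and 5421 lower at 5 h. Of these, 2789 were at least 2-fold higher and 2922 at least 2-fold lower, while 178 were at least 8-fold higher and 426 at least 8-fold lower. In 11395 tested genes (76.3%) the 3 values of one group all lay above those of the other, which chance alone gives for 10% of genes. Against a change of 1.5-fold, instead of no change, 6721 genes passed. The labels do not say that the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

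The 10 genes that rose most by the rule for named genes held 6 of amino acid uptake or synthesis. The cystine transporter gene Slc7a11 (chromosome 3, 49892526 to 50443614) had 1 of 37640616 counts in the 0 h group and 1226 of 50260127 in the 5 h group, a ratio of 918 with an exact binomial 95% interval of 164 to 36300 that covers counting error only. That count was in 0 h replicate 3, and the other 0 h libraries had 0. The glycine transporter gene Slc6a9 (chromosome 4, 117834506 to 117875198) went from 0.56 ± 0.47 to 136.5 ± 10.6 CPM (counts-per-million; mean ± SD, n = 3 per group, here and below), with a log2 fold change of 7.97 (SE 0.23). Asns, which encodes asparagine synthetase (chromosome 6, 7675169 to 7693254), went from 1.85 ± 0.01 to 120.3 ± 8.78 CPM, and its log2 fold change was 6.02 (SE 0.11). The proline synthesis gene Pycr1, the alanine transaminase gene Gpt2 and the cationic amino acid transporter gene Slc7a3 rose by 6.44 (SE 0.27), 6.16 (SE 0.25) and 6.11 (SE 0.28) on the log2 scale. These folds rest on few counts at 0 h: without 0 h replicate 3 Pycr1 was at 7.39, and without 0 h replicate 1 Slc7a3 was at 6.71 and Slc6a9 at 8.72. Chac1, whose product degrades glutathione, rose by 7.41 (SE 0.22). Il2 (chromosome 3, 37120523 to 37125959) went from 1.13 ± 0.57 to 74.9 ± 8.04 CPM, a log2 fold change of 6.02 (SE 0.22). Lad1, which encodes a basement membrane filament protein, rose by 6.14 (SE 0.10) on the log2 scale, and Tnnt2, the cardiac troponin T gene, by 5.62 (SE 0.14). Tnnt2 lies 3011 bp past the end of Lad1 on the same strand of chromosome 1, and gene counts alone cannot tell its own transcripts from reads that run on from Lad1. The largest adjusted p among these 10 genes in edgeR's test was 1.52e-08.

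Of the 10 genes that fell most, 3 were neighbouring heat shock genes of chromosome 17. Hspa1b (34956436 to 34959238) went from 8097 ± 187 to 60.9 ± 6.84 CPM, a log2 fold change of -7.06 (SE 0.11), and Hspa1a (34969190 to 34972156) from 7541 ± 81.6 to 74.7 ± 15.4 CPM, or -6.66 (SE 0.16). These are near-identical copies, so how their reads divide between them is uncertain; together they took 1.48% ± 0.017 of all counts at 0 h and 0.0143% ± 0.0023 at 5 h. Hspa1l, beside them, fell by 6.39 (SE 0.12) on the log2 scale. Igfbp4, which encodes a binding protein of insulin-like growth factors, went from 410.9 ± 17.2 to 4.24 ± 0.83 CPM, a log2 fold change of -6.59 (SE 0.12). The transcription factor gene Fosb had a log2 fold change of -5.92 (SE 0.16). Ggt1 (glutathione breakdown), the microRNA gene Mir150, Trim72 and Fam222a had log2 fold changes between -5.97 and -5.79. The largest adjusted p among the genes named here in edgeR's test was 2.36e-08.

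**Figure D1:**
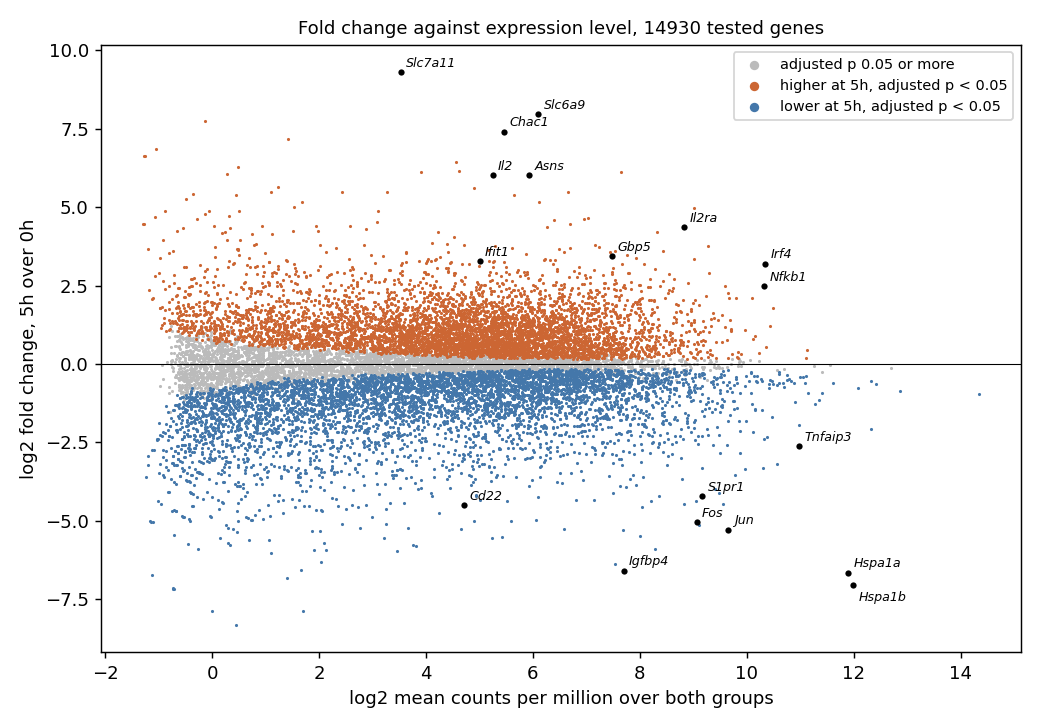
Log2 fold change at 5 h over 0 h (vertical axis) against the log2 mean CPM of both groups (horizontal axis) for 14930 tested genes, 1 point per gene, coloured by whether edgeR's adjusted p was under 0.05. Of these genes, 5584 were called higher and 5421 lower, with Slc7a11 (1 count in the 0 h group, so its fitted value depends on the prior count) at the top and Hspa1a and Hspa1b at the lower right among the labelled genes.

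Most interferon-stimulated antiviral genes were higher at 5 h. Of 50 tested members, 43 rose, 4 fell and 3 did not pass edgeR's test, with a median log2 fold change of 1.06; the counts were the same adjusted over the list alone. Ifit1, whose product binds viral RNA (chromosome 19, 34640871 to 34650009), went from 6.06 ± 0.63 to 58.1 ± 6.51 CPM, a log2 fold change of 3.27 (SE 0.13, adjusted p = 4.3e-09). Ifi44 rose by 3.33 (SE 0.13), the RNA sensor gene Ifih1 by 2.16 (SE 0.10), Rsad2 (viperin, which makes a nucleotide that halts viral RNA synthesis) by 1.96 (SE 0.16), Lgals3bp by 1.5 (SE 0.06) and the ubiquitin-like modifier gene Isg15 by 1.34 (SE 0.17). Irf7, the main inducer of interferon alpha genes, rose by 0.26 (SE 0.06, adjusted p = 0.00346), but with upper-quartile scaling its log2 fold change was 0.13 and it no longer passed (adjusted p = 0.0838). The members that fell were Ifi204, Oas2, Herc6 and Ifi203, at -0.93 to -0.32; with total counts as the only scaling, 2 members fell. Irf9, Samd9l and Oas1g had log2 fold changes of 0.03, 0.20 and 0.43. As a list these genes ranked above all other tested genes by camera (adjusted p = 1.16e-07), with an adjusted p = 0.274 when the correlation between genes was estimated. Over the same interval, 30 of 35 tested markers of B cells, myeloid cells and dendritic cells fell and 5 rose, leaving out Bst2, a dendritic cell marker that is also in the interferon-stimulated list.

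Most genes on the list of interferon gamma inducible genes also rose. Ifng itself did not pass edgeR's test, and which signal raised these genes was not tested. Of 22 tested guanylate-binding proteins, immunity-related GTPases, chemokines and regulators, 19 rose and 3 fell (Ciita, Irf1 and Socs1), the same adjusted over the list alone, with a median log2 fold change of 1.37. Gbp5, which acts in inflammasome assembly, went from 30.02 ± 3.28 to 325.9 ± 26.3 CPM, a log2 fold change of 3.44 (SE 0.10). The transcription factor gene Irf8 rose by 2.35 (SE 0.10), the GTPase gene Tgtp1 by 2.31 (SE 0.09) and Gbp7 by 1.85 (SE 0.06). Tgtp1 and the Gbp genes have close paralogs, so how their reads divide is uncertain. Camera gave an adjusted p = 1.5e-05 for this list, and an adjusted p = 0.229 with an estimated correlation.

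The interferon genes themselves were scarce, apart from Ifng. Ifnb1 (chromosome 4, 88522025 to 88522774) had 0 counts in each 0 h library and 13, 10 and 15 counts in the 5 h libraries. Its 5 h rate was 9.49-fold that of a floor of 3 counts over the 0 h group. Folds against this floor, here and below, use total counts without TMM scaling and leave out the counting error at 5 h. Ifnb1 was too low for the main test. Without a filter on low counts its adjusted p in edgeR was 2.05e-06. Ifna4 had 0 counts at 0 h and 6, 8 and 5 at 5 h, or 4.74-fold the floor. Ifna2 had 0 counts at 0 h and 2, 5 and 2 at 5 h, or 2.25-fold the floor. Without the filter, edgeR's adjusted p was 0.00113 for Ifna4 and 0.0366 for Ifna2. Both were chosen after their values were seen, and alpha interferon genes are near-identical copies whose reads may be shared. Ifng, the interferon of activated T cells, had 53.7 ± 6.33 CPM at 0 h and 57.3 ± 10.7 at 5 h, a log2 fold change of 0.09 (SE 0.14) that did not pass edgeR's test (adjusted p = 0.564). It lay at -0.04 with upper-quartile scaling, and at 0.25 without 5 h replicate 3, where it passed (adjusted p = 0.0262).

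Sensors of viral nucleic acid moved both ways. Of 23 tested members of the sensing list, 13 rose and 7 fell, the same adjusted over the list alone, with a median log2 fold change of 0.66. Besides Ifih1, the regulator gene Dhx58 rose by 1.15 (SE 0.10) and the nucleic acid sensor gene Zbp1 by 0.90 (SE 0.07). Ddx58, which encodes the RNA sensor RIG-I (chromosome 4, 40203773 to 40239828), went from 95.1 ± 5.57 to 66.7 ± 7.97 CPM, a log2 fold change of -0.51 (SE 0.09, adjusted p = 0.000607 by edgeR). Unc93b1, the chaperone of endosomal Toll-like receptors, had a log2 fold change of -1.36 (SE 0.12). Tmem173, Samhd1 and Irf5 did not pass, at -0.08, 0.12 and 0.19. Camera did not call the list (adjusted p = 0.216). Ifih1 and Zbp1 belong to the interferon-stimulated list too, as does Ifi204.

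Early activation genes and T cell cytokine genes were mostly higher at 5 h. Of 24 tested early activation genes, 16 rose and 4 fell (Cd24a, Nr4a1, Nr4a2 and Cd40lg), with a median log2 fold change of 1.04. Il2ra (chromosome 2, 11642807 to 11693193) went from 42.5 ± 1.87 to 870.4 ± 75.2 CPM, a log2 fold change of 4.36 (SE 0.09). The large neutral amino acid transporter gene Slc7a5 rose by 3.33 (SE 0.07), the transcription factor gene Irf4 by 3.20 (SE 0.07), reaching 2354 ± 120 CPM, and the costimulatory receptor gene Tnfrsf9 by 2.35 (SE 0.07). Cd69, an early activation antigen, was already at 540.3 ± 21.4 CPM at 0 h and rose by 1.06 (SE 0.08). Icos, Egr1, Rel and Batf did not pass, at -0.08 to 0.14. Of 24 tested cytokine and chemokine genes, 19 rose, 4 fell (Ccl5, Il10, Fasl and Ltb, at -2.64 to -0.35) and Ifng did not pass, with a median log2 fold change of 2.81. Besides Il2, the chemokine gene Ccl4 rose by 4.64 (SE 0.14), Tnfsf14 by 3.50 (SE 0.12) and Lif by 3.20 (SE 0.11). Both counts were the same adjusted over the list alone. Camera gave adjusted p = 0.00136 for the activation list and 0.000353 for the cytokine list; with an estimated correlation the adjusted p was 0.219 for activation and 0.292 for cytokines. With only genes at 10 CPM or more in 3 or more libraries, 11 cytokine genes rose.

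NF-kB genes divided. Of 22 tested feedback and target genes, 12 rose and 9 fell, the same adjusted over the list alone, with a median log2 fold change of 0.68, and Rel did not pass at 0.10. The survival gene Bcl2l1 rose by 3.71 (SE 0.07), Nfkb1, a subunit of the factor itself, by 2.48 (SE 0.06) from 389.4 ± 8.3 to 2180 ± 73.3 CPM, and the adaptor gene Traf1 by 1.19 (SE 0.06). Tnfaip3, the feedback inhibitor A20, had 3476 ± 54.6 CPM at 0 h and 564.8 ± 33.5 at 5 h, a log2 fold change of -2.62 (SE 0.07). Camera did not call the list (adjusted p = 0.268). In the myeloid inflammatory list only 7 of 20 members in the table were tested. Il1a and Il23a rose, with 96 counts of Il1a at 5 h against 0 at 0 h (24-fold the floor of 3 counts). Il1b, Cxcl2 and Ptgs2 fell, at -3.29 (SE 0.41), -1.74 (SE 0.36) and -1.43 (SE 0.33), and Irg1 and Osm did not pass, at -0.58 and -0.24; with upper-quartile scaling 5 members fell, and with a filter at 10 CPM 0 passed in either direction. The count was the same adjusted over the list alone. The list's median was -0.58 and its mean 0.37, which became -0.08 with Il1a set at its fold against the floor. Camera put the list lower (adjusted p = 0.538), while fry, a test of whether a list's genes move one way on balance, put it higher (adjusted p = 7.73e-05).

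Genes of resting T cells fell. Of 23 tested naive and quiescence genes, 19 fell and 4 rose (Foxp1, Bach2, Satb1 and Slfn2), the same adjusted over the list alone, with a median log2 fold change of -2.28. S1pr1, the receptor for exit from lymphoid tissue (chromosome 3, 115710433 to 115715072), went from 1093 ± 28.9 to 58.5 ± 4.42 CPM, a log2 fold change of -4.22 (SE 0.08). The chemokine receptor gene Cxcr4 was at -4.38 (SE 0.08), the glucocorticoid-induced gene Tsc22d3 at -3.86 (SE 0.09) and the transcription factor gene Tcf7 at -2.58 (SE 0.06). The adjusted p by camera was 1.64e-06, and with an estimated correlation the adjusted p was 0.216. B cell markers fell over the same interval, in 16 of 17 tested.

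T cell receptor and lineage genes moved both ways. Of 20 tested, 6 rose, 11 fell and Trbc2, Cd2 and Trbc1 did not pass, at -0.03, 0.09 and 0.11; the median log2 fold change was -0.41 and camera did not call the list (adjusted p = 0.185). Cd8b1 was at -2.13 (SE 0.07), Cd28 at -1.92 (SE 0.07) and Cd8a at -1.45 (SE 0.07), while the signalling adaptor gene Lcp2 rose by 1.68 (SE 0.08). Thy1, which encodes CD90, the antigen used for isolation, went from 390.2 ± 8.24 to 180.6 ± 9.79 CPM, a log2 fold change of -1.11 (SE 0.07). Of 15 tested inhibitory receptors and ligands, 10 rose, 4 fell (Socs3, Ctla4, Entpd1 and Lag3) and Tigit did not pass at -0.07, with a median of 1.34. Cd200 rose by 3.10 (SE 0.11) and Cish by 1.55 (SE 0.07), and Socs3 and Ctla4 were at -4.55 (SE 0.12) and -1.80 (SE 0.08). With total counts as the only scaling, 2 of these members fell. Camera called this list weakly (adjusted p = 0.0412), and the call was lost with an estimated correlation (adjusted p = 0.219), with total counts as the only scaling (0.0571), with a filter at 10 CPM (0.145) and without 0 h replicate 1 (0.0682). Counts in both lists were the same adjusted over the list alone.

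Antigen processing genes of MHC class I moved both ways. Of 20 tested, 5 rose (Tap1, Tapbp, Psme1, Erap1 and Psme2), 10 fell, and Tap2, H2-T23, Nlrc5, B2m and Psmb9 did not pass, at -0.07 to 0.13. The proteasome activator gene Psme2 rose by 2.09 (SE 0.07), the peptide-trimming enzyme gene Erap1 by 1.73 (SE 0.09) and the peptide-loading gene Tapbp by 1.11 (SE 0.06). H2-T22, a class I heavy chain with close paralogs, was at -1.0 (SE 0.06). The median was -0.18 and the mean 0.05; camera put the list lower (adjusted p = 0.514) and fry higher (adjusted p = 0.345), neither past the threshold. The count was the same adjusted over the list alone.

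Ribosome biogenesis genes rose without exception in edgeR's test: 30 of 30, also adjusted over the list alone, with a median log2 fold change of 2.23. Rrp1b rose by 2.59 (SE 0.07), Heatr1 by 2.48 (SE 0.07), Rrp9 by 2.44 (SE 0.07) and Mybbp1a by 2.25 (SE 0.06), the last from 277.2 ± 6.64 to 1321 ± 19.5 CPM. Camera gave an adjusted p = 3.47e-14, and an adjusted p = 0.083 with an estimated correlation. Messages for the ribosomal proteins themselves went the other way by a smaller amount: 20 of 36 fell, 0 rose and 16 did not pass, also adjusted over the list alone, with a median of -0.39. Rps21 was at -0.84 (SE 0.13), Rps15 at -0.66 (SE 0.08), Rplp1 at -0.54 (SE 0.09) and Rplp0 at -0.50 (SE 0.07). With upper-quartile scaling 31 fell, with total counts as the only scaling 13 fell and 1 rose, and without 5 h replicate 3, 2 rose and the median was -0.25. Camera gave adjusted p = 0.00362 for this list and adjusted p = 0.474 with an estimated correlation. Ribosomal protein genes have many processed copies, and rows annotated as pseudogenes held 11.8% ± 0.44 of counts at 0 h and 10.5% ± 0.72 at 5 h, so their values are uncertain.

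Metabolic lists were mixed. Of 21 glycolysis genes 8 rose, 10 fell, and Pfkl, Tpi1 and Pkm did not pass, at -0.11, -0.03 and 0.12. Gapdh is among the 21 with a mean of only 252.3 counts per library, and may have lost reads to its processed copies. Hexokinase gene Hk2 rose by 2.46 (SE 0.10), Ldha by 1.22 (SE 0.07) and the monocarboxylate transporter gene Slc16a1 by 1.2 (SE 0.09), while the glucose transporter gene Slc2a3 was at -1.62 (SE 0.09). The median was -0.11, or 0.05 with total counts as the only scaling; camera gave adjusted p = 0.872 (lower) and fry adjusted p = 0.361 (higher). Of 19 sterol genes, 10 rose and 5 fell, among them Mvk, Dhcr7, Insig1 and Mvd, and 4 did not pass, among them Sc5d, Stard4 and Cyp51 at -0.14, -0.06 and 0.05. Sqle and Fdps rose by 1.70 (SE 0.08) and 1.19 (SE 0.10), and Mvk and Insig1 were at -2.90 (SE 0.10) and -0.88 (SE 0.07). The median was 0.15 and camera's adjusted p 0.454; with upper-quartile scaling 8 sterol genes fell. Both counts were the same adjusted over the list alone.

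Most cell cycle genes were lower at 5 h. Of 29 tested, 22 fell and 5 rose (Cdk4, Cdk6, Ccnd2, Mcm5 and Mcm2), the same adjusted over the list alone, with a median of -1.08 (-0.34 over the members left by a filter at 10 CPM), and Pcna and Mcm3 did not pass, at 0.03 and 0.13. Cdk4 and Cdk6, kinases of the G1 phase, rose by 1.78 (SE 0.07) and 1.46 (SE 0.07), while Ccnd3 was at -2.29 (SE 0.10) and the proliferation marker Mki67 at -2.04 (SE 0.10). With upper-quartile scaling, 3 rose. Camera gave adjusted p = 0.00772, lost with an estimated correlation (adjusted p = 0.185) and with a filter at 10 CPM (adjusted p = 0.311), where 9 members fell. B cell markers fell over the same interval, in 16 of 17 tested, with a median of -2.16.

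Immediate early and heat shock genes, which many cells induce during handling, were at high levels at 0 h and fell by 5 h. Of 24 tested, 20 fell, 2 rose (Hspd1 and Atf3, at 0.28 and 0.34) and Hspe1 and Dusp2 did not pass, at -0.19 and -0.13; the count was the same adjusted over the list alone and the median was -2.85. With upper-quartile scaling 1 member rose. Besides Hspa1a, Hspa1b and Fosb, Fos (chromosome 12, 85473890 to 85477273) went from 1039 ± 13.4 to 31.3 ± 1.06 CPM, a log2 fold change of -5.05 (SE 0.07). Jun was at -5.29 (SE 0.11) and the co-chaperone gene Dnajb1 at -4.46 (SE 0.08). Camera gave adjusted p = 2.92e-08, and adjusted p = 0.185 with an estimated correlation. The share of counts in rows that resemble ribosomal RNA went from 3.0% ± 0.49 to 1.61% ± 0.29 over the same interval.

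The list of integrated stress and unfolded protein genes held members of opposite behaviour. Of 21 tested, 11 rose, 7 fell and Pdia4, Sdf2l1 and Xbp1 did not pass, at -0.11, 0.03 and 0.13. Besides Slc7a11, Chac1 and Asns, the serine synthesis gene Psat1 rose by 4.20 (SE 0.08), whereas the phosphatase subunit gene Ppp1r15a was at -2.59 (SE 0.07). The median was 0.28, the mean 1.57, and camera's adjusted p 0.163. Of 19 apoptosis and p53 target genes, 5 rose (Aen, Bid, Bax, Bak1 and Cdkn1a) and 7 fell, with a median of -0.16 and camera's adjusted p at 0.3. Aen and Bid rose by 3.04 (SE 0.15) and 2.88 (SE 0.11), and Pmaip1 and Sesn1 were at -3.25 (SE 0.10) and -2.17 (SE 0.09). Both counts were the same adjusted over the list alone.

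Markers of other spleen cells were detected at 0 h and were mostly lower at 5 h. Of 17 tested B cell markers, 16 fell and Pou2af1 rose (1.34), with a median of -2.16. Cd22 went from 50.04 ± 2.96 to 2.21 ± 0.54 CPM, a log2 fold change of -4.50 (SE 0.15). Cr2 was at -3.40 (SE 0.15), Cd79a at -3.22 (SE 0.13) and Pax5 at -2.98 (SE 0.15). The adjusted p by camera was 7.87e-06, and the adjusted p was 0.083 with an estimated correlation. With a filter at 10 CPM, 10 B cell markers were left that fell. Of 9 monocyte, macrophage and neutrophil markers, 7 fell, such as Itgam at -3.26 (SE 0.25) and Cd68 at -1.27 (SE 0.16), and 2 rose, Hmox1 by 3.05 (SE 0.14) and Mpeg1 by 2.29 (SE 0.16). Their median was -1.99 (camera adjusted p = 0.253), and 0.82 over the members left by a filter at 10 CPM, where 2 fell; without a filter on low counts 11 fell. Of 10 dendritic cell markers, 7 fell and 3 rose (Zbtb46, Xcr1 and Bst2), with a median of -1.31 (camera adjusted p = 0.151). The MHC class II genes Cd74, H2-Aa and H2-Eb1 were at -2.31 (SE 0.12), -2.16 (SE 0.13) and -1.63 (SE 0.11), and Zbtb46 rose by 3.70 (SE 0.26). Only 1 dendritic cell marker rose with a filter at 10 CPM.

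Of 7 natural killer cell markers, 4 fell (Eomes, Gzma, Prf1 and Il2rb), Gzmb rose, and Klrk1 and Klrb1c did not pass, at 0.30 and 0.74. Adjusted over the list alone, 2 rose, as they did without 0 h replicate 3, without 5 h replicate 1, without pseudogene rows and without a filter on low counts, and 3 rose with total counts as the only scaling. Eomes was at -2.35 (SE 0.12), Prf1 at -1.96 (SE 0.09), Il2rb at -0.65 (SE 0.07) and Gzmb at 0.84 (SE 0.10); all are also expressed by cytotoxic T cells. The median was -0.65 (camera adjusted p = 0.268), and it ranged from -1.89 (without 5 h replicate 2) to -0.19 (without 0 h replicate 3) when 1 library was left out. All 6 tested erythroid and platelet markers fell, with a median of -2.29, among them Slc4a1 at -4.97 (SE 0.53), Hbb-bs at -2.89 (SE 0.27) and the copies Hba-a1 and Hba-a2 at -2.39 (SE 0.29) and -2.19 (SE 0.21). Slc4a1 ranged from -5.67 (without 5 h replicate 1) to -4.37 (without 5 h replicate 3). With a filter at 10 CPM, 1 was left that fell, at -0.43. Camera gave adjusted p = 0.0176, and adjusted p = 0.219 with an estimated correlation. Of 13 mitochondrially encoded transcripts 12 fell, with a median of -0.51 (-0.32 without 5 h replicate 1), and ND3 did not pass at -0.15. COX1 was at -0.87 (SE 0.07), ATP6 at -0.74 (SE 0.10), COX2 at -0.59 (SE 0.12) and ND4 at -0.51 (SE 0.11). With total counts as the only scaling 6 fell; camera gave adjusted p = 0.0144, and adjusted p = 0.475 with an estimated correlation. Other than for natural killer cells, counts in these marker lists and in the mitochondrial list were the same adjusted over the list alone. Members named only to make up a count of 5 or fewer, here and in the lists above, were chosen after their values were seen.

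Camera called 13 of 25 tested lists, 6 higher and 7 lower, with a preset correlation between genes, and 0 with an estimated correlation. With its preset correlation camera also called between 8 and 11 lists when the same 6 libraries were split in ways that mix the times, where part of the difference between the times remains. The estimated correlation was below the preset 0.01 for B cell markers (-0.0333), inhibitory receptors (-0.0473) and cell cycle (-0.00933). It was above 0.01 for the other called lists. In those below it, the loss of the call comes from the fewer degrees of freedom, not from a higher correlation. Fry called 23 of the 25 lists at the real split.

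**Figure D2:**
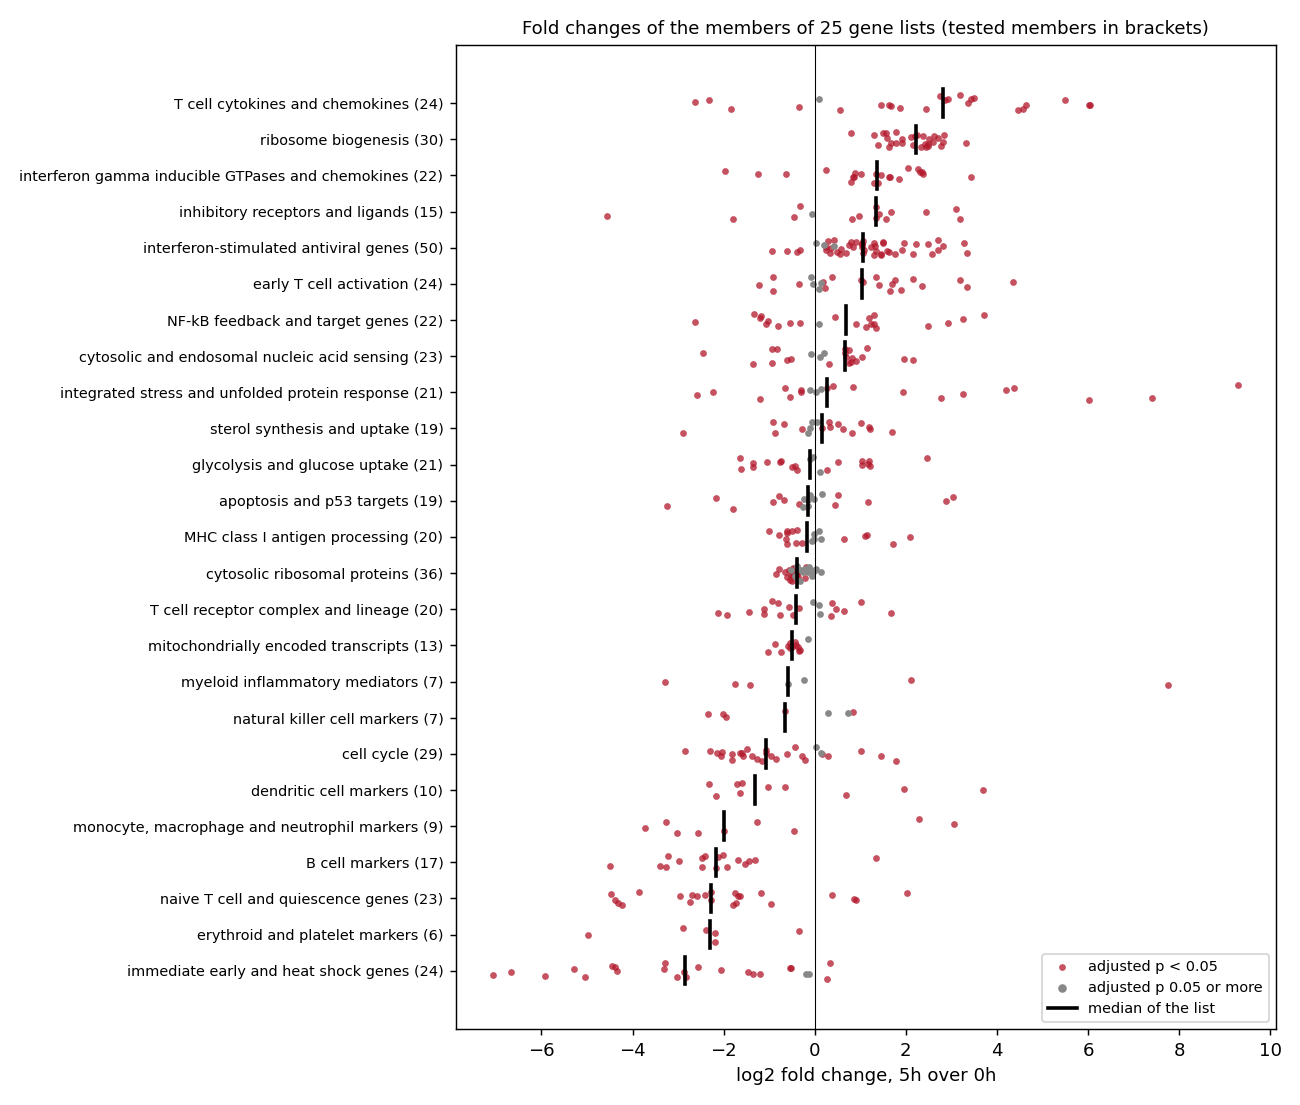
Log2 fold changes at 5 h over 0 h (horizontal axis) of the tested members of 25 gene lists, 1 row per list and 1 point per gene, red where edgeR's adjusted p was under 0.05 and grey otherwise, with black bars at each list's median. Medians run from 2.81 for T cell cytokines and chemokines to -2.85 for immediate early and heat shock genes; the points of Slc7a11 and Il1a (1 and 0 counts in the 0 h group) are fitted values that depend on the prior count.

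**Figure D3:**
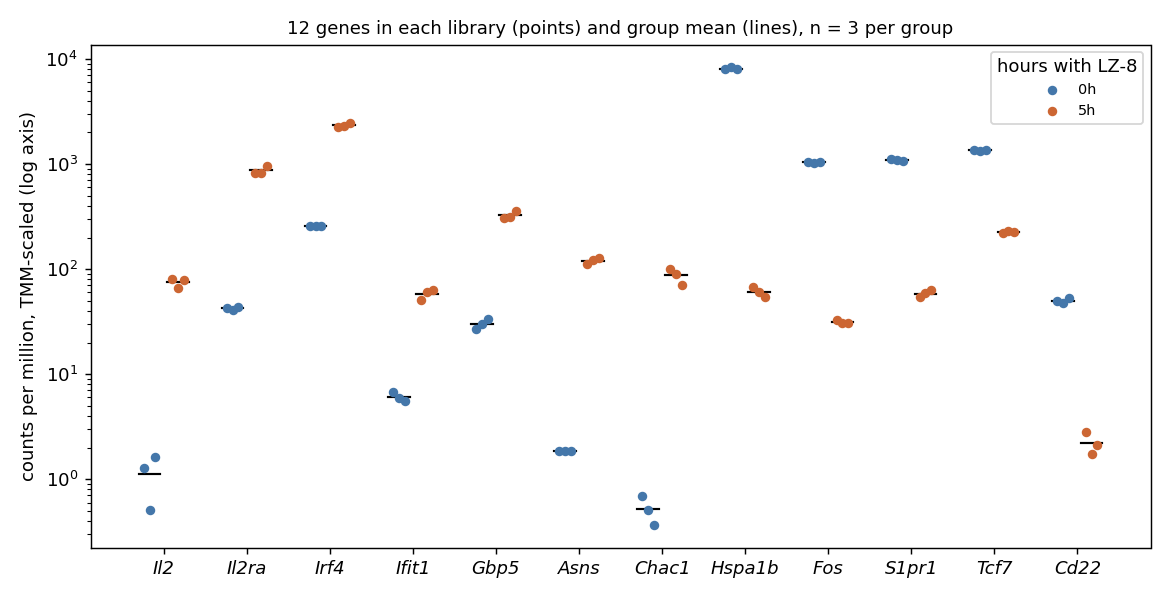
CPM values (TMM-scaled, log axis) of 12 genes in each library (points, 3 per group) with the group mean (line), for 0 h in blue and 5 h in orange. The 3 values of one group lie wholly above those of the other for each of the 12 genes, with Il2, Il2ra, Irf4, Ifit1, Gbp5, Asns and Chac1 higher at 5 h and Hspa1b, Fos, S1pr1, Tcf7 and Cd22 lower.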

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

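The 3 alternatives that thinned the counts, left out pseudogene rows or scaled without heat shock, ribosomal RNA-like and mitochondrial rows were chosen after seeing the data. Most named genes were picked for a large change or a low adjusted p, which favours their keeping it. Over 17 alternatives and 2080 comparisons of named genes, 2075 kept their direction and side of the threshold. The exceptions were Irf7, at 0.125 and past the threshold no longer with upper-quartile scaling, and Ifng, at -0.0392 with upper-quartile scaling and between -0.00691 (without 5 h replicate 1) and 0.245 (without 5 h replicate 3, where it passed) when 1 library was left out, -0.00387 without 0 h replicate 1; the cause was not tested. The count of changed genes was 10344 to 11359 with 1 library left out. Otherwise it was between 7638 (filter at 10 CPM) and 12300 (no filter), except 6721 against a 1.5-fold change, which asks for more. Calls shared with the main result, all in the same direction, were 10054 with DESeq2, 10871 with limma-voom, 10343 with upper-quartile scaling, 10246 with total counts only and 10339 after thinning. With 10 CPM, 3321 genes changed at least 2-fold, as fewer genes were tested (9370). With the replicate number as a block, 10599 genes were called and no named gene or list changed its side; the numbers are not known to pair the libraries, since same-numbered libraries deviated with correlations of -0.106, -0.0208 and -0.181 and did not each correlate best with their own number. Among lists, inhibitory receptors lost their call with total counts only (0.0571) and 10 CPM (0.1445), and ranged from 0.0351 (without 5 h replicate 2) to 0.0682 (without 0 h replicate 1); cell cycle lost it at 10 CPM (0.3108). Without a filter, nucleic acid sensing (0.0485), integrated stress (0.0262) and dendritic cell markers (0.0485) passed. These are camera's adjusted p-values, and the causes were not tested. With an estimated correlation, and so 4 degrees of freedom, every called list lost its call. Camera's adjusted p was then 0.0830 for ribosome biogenesis and B cell markers, and 0.1849 for cell cycle and for immediate early and heat shock genes. It was 0.2162 for naive genes and 0.2186 for activation, inhibitory receptors and erythroid markers. Interferon gamma GTPases were at 0.2293, interferon-stimulated genes at 0.2737 and cytokines at 0.2924. Ribosomal proteins were at 0.4737 and mitochondrial transcripts at 0.4749. Fry, which does not compare a list with other genes, passed 10 more lists: nucleic acid sensing (0.000942), NF-kB (6.39e-05), myeloid inflammatory mediators and natural killer markers (both 7.73e-05), T cell receptor and lineage (3.19e-06), integrated stress (1.92e-06), apoptosis (0.000677), sterol (0.00112), monocyte, macrophage and neutrophil (0.0207) and dendritic cell markers (3.74e-05). Depth limits genes with 0 counts at 0 h, such as Ifnb1, Ifna4, Ifna2 and Il1a, to a fold against a floor.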

Other observations

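The 8 gene lists added in this part were chosen after the values were seen. So were the tests on other cell types, on endoplasmic reticulum stress, on the synthetases and on members outside the most abundant rows. The machinery that charges transfer RNA with amino acids rose as a group in the cytosol: 19 of 20 cytosolic aminoacyl-tRNA synthetase genes rose and Qars fell (-0.28), with a median log2 fold change of 2.24. Of 16 mitochondrial synthetase genes, 10 rose, Cars2 and Fars2 fell, and the median was 0.35. Of 16 genes of serine, glycine, proline and folate metabolism, 15 rose and Got1 fell (-1.13), with a median of 3.98. Of 12 amino acid transporter genes, 10 rose, Slc38a2 fell (-1.19) and Slc43a1 was at 0.29, with a median of 2.74. Genes for protein turnover and folding also rose: 30 of 31 proteasome subunit genes, with a median of 1.19 and Psmb1 at 0.07, and 8 of 8 cytosolic chaperonin subunit genes, with a median of 0.96. Camera's adjusted p with an estimated correlation was 0.00924 for cytosolic synthetases, 0.298 for mitochondrial ones, which the preset correlation did not call either (0.0856), 0.0106 for serine and related metabolism, 0.0652 for transporters, 0.016 for the proteasome and 0.0419 for the chaperonin. As these lists were picked for having been seen to move, these p-values are not independent evidence.

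In the first pattern, 43 of 50 interferon-stimulated antiviral genes rose. An increase in other cell types would raise their markers, but 35 tested markers of B cells, myeloid cells and dendritic cells (without Bst2, which the interferon list holds) had a median log2 fold change of -1.99 (95% bootstrap interval -2.31 to -1.59). Their most abundant, Cd74, went from 214.3 to 43.1 CPM. Of these markers 17 were of B cells, so the pooled median says less of the others. Of 9 myeloid markers 7 fell and 2 rose, with a median of -1.99, or 0.82 over members left by a filter at 10 CPM. Of 10 dendritic cell markers, counting Bst2, 7 fell and 3 rose. Camera called neither list (adjusted p = 0.253 and 0.151), so a rise of myeloid or dendritic cells is not settled. After thinning each library to the smallest total the list median was 1.09 (0.76 to 1.40). Thinning keeps the expected share of each gene, so a scaled median stays near its value and this cannot decide on depth. Once a trend on gene length and GC content was removed, the median was 1.22 (0.81 to 1.38). Across genes that trend took only 4.06% of the variance of fold changes, with rank correlations of -0.0446 for length and -0.161 for GC. Its removal could therefore move the median little, and the weakness of the trend is what argues against such a bias. Hours in culture without LZ-8 also stay open. The series has 0 untreated libraries at 5 h, so an effect of LZ-8 and one of culture after isolation cannot be told apart for these genes. Both, and interferon made by a few cells in the culture, remain untested candidates; Ifnb1 counts of 13, 10 and 15 at 5 h are a measured fact beside them.

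In the second pattern, 20 of 24 immediate early and heat shock genes fell, from levels at which Hspa1a and Hspa1b took 1.48% of counts. Rows that take many counts shift every other gene of a library by the same factor. The 10 most abundant rows of a library held 8.53% ± 0.53 of counts at 0 h and 5.07% ± 0.24 at 5 h. A smaller share at 5 h would raise other genes, so it could not lower the rest of the list. The 20 members outside these rows in all libraries had a median -2.85 from that of all other tested genes (95% bootstrap interval -3.83 to -1.27). As 20 of 24 members were already known to fall, this value could be foreseen and is no separate support. Scaling without the abundant rows moved the list only from -2.85 to -2.86 and decides nothing. After thinning each library to the smallest total the median was -2.87 (-4.32 to -1.35). That interval reaches above the -1.5 set beforehand as the bound against library depth. Thinning keeps the expected share of each gene, so the scaled median stays near its value and this cannot decide on depth. An isolation response fading in culture is also left open: with 0 untreated libraries at 5 h, it cannot be told apart from an effect of LZ-8 on these genes.

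In the third pattern, 17 of 17 amino acid response genes, among them Slc7a11, Chac1, Asns and Psat1, rose, with a median of 5.39. This list was chosen after the values were seen, so its count is not evidence of a uniform rise. In the fixed list of integrated stress and unfolded protein genes, 11 of 21 rose and 7 fell, the latter with Ppp1r15a at -2.59. For endoplasmic reticulum stress, the bound was a median rise of 1 or more on the log2 scale in 9 chaperone and unfolded protein genes. That bound was chosen after the values were seen. The 9 genes had a median of -0.11 (95% bootstrap interval -0.55 to 0.28). Of them, 2 were higher (Pdia6, and Creld2, which is lost when adjusted over the list alone) and 4 lower (Dnajb9, Hspa5, Hsp90b1 and Herpud1). This speaks only of these genes, and a stress of that compartment that leaves them unchanged was not tested. Once the trend on length and GC content was removed, the median was 5.61 (4.06 to 6.66). A trend this weak, with 4.06% of the variance, could not undo the rise of a list picked for it, so that median decides nothing. Only the weakness of the trend itself argues against such a bias. An amino acid response, which is known to act on cytosolic synthetase genes, would raise them above mitochondrial ones, and their medians differed by 1.89 (1.17 to 2.60); this is consistent with such a response as a hypothesis only, since Iars had been seen among the genes that rose most. Whether LZ-8, growth after activation or a shortage of amino acids in the medium is behind it was not tested, as no library separates them.

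Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 11005 changed genes, 5584 higher, 5421 lower and 5711 changed at least 2-fold by edgeR, and the highest of the other splits gave 0 for each of these 4 counts; in each case 1 of 10 splits, the real one, gave a count as large. Camera with its preset correlation called 13 lists in the real split and up to 11 in another, with 1 of 10 splits reaching 13. The others all mix the times, with 2 libraries of one time and 1 of the other on each side. Part of the difference between the times therefore remains in them, so their list calls are no measure of calls without a change, and the spread that the times add within each side bears on edgeR's count of 0.

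At 5 h, replicate 3 stood apart from the other libraries of its group. The correlation of log2 CPM across genes was 0.986 between 5 h replicates 1 and 3, 0.990 between replicates 2 and 3, and 0.993 between replicates 1 and 2, against 0.991 to 0.992 between 0 h libraries. On the second principal component, 5 h replicates 1, 2 and 3 lay at -24.4, -5.93 and 29.9.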
